A study of Rattus norvegicus with 15 samples.

How the data were processed

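Peripheral blood DNA of 15 rats, 3 in each of 5 groups, was measured on 2-colour Agilent arrays, with MeDIP DNA in the Cy5 channel and input DNA in the Cy3 channel, per the labels. Per the file headers, the deposited scanner files came from Feature Extraction 11.0.1.1, and probe positions refer to the rn4 assembly of the rat genome, version 3.4. The deposited scanner files hold an intensity per spot and channel: raw medians, background medians, and processed signals that are background-subtracted and dye-normalised with a linear method per the file headers. They also hold the authors' log10 ratio of Cy5 over Cy3 per spot. The processed signals gave the same ratio within 0.001 on the log2 scale for 99.3% to 99.9% of probes of an array. The authors' deposited value table was taken as log2, an assumption, since its log base, centring and direction are not given in the sources used here. Per the submitters' processing notes limma was used, with no role stated. The columns of that value file correlated with the log2 ratios of the same arrays at 0.846 to 0.886, with medians of 0.01 to 0.05, and neighbouring probes correlated at 0.812 to 0.855 in that file and at 0.350 to 0.509 in the scanner values, so its values may have been smoothed. It served as an alternative.

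From the scanner files, log2 of the Cy5 over the Cy3 processed signal was taken for 172669 probes on each array, after 6856 control spots were left out. Spots marked as outliers, 235 to 10700 per array and most in LTF, were left out, and saturated spots, at most 19 per array, were kept. Each array was centred on its median, which was between -0.11 and -0.01 before centring, with no loess or quantile step, as is usual where many probes carry signal. The named promoters foreseen before the data were examined could not be used, because the files do not pair probes with genes, so the rule set beforehand for that case was applied. Probes of a chromosome with gaps of at most 500 bp were joined into runs, and runs of at least 3 probes were kept as regions. Of 17668 runs, 884 had too few probes and 2 lacked a value on some array, which left 16782 regions with 171421 probes. Keeping these 2 regions is among the alternatives. Tests of gene lists, of germline against housekeeping promoters and of blood cell markers, all planned, were not possible without gene names, and no change in blood cell makeup can be weighed here.

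No arrays held identical values, and the log2 ratios of pairs of arrays correlated at 0.814 to 0.954. Region means were fitted with limma (lmFit and eBayes) with a mean for each of the 5 groups and a shared estimate of the spread over all 15 arrays, and p-values were adjusted by the Benjamini-Hochberg method over regions within each comparison, with a threshold of 0.05. The main comparisons were the DR model with control and each treatment with the DR model. Secondary ones were LTF with each other treatment, the mean of the 4 diabetic groups with control, and the mean of the 3 treated groups with the DR model. The regions named were, for each main comparison, the 8 higher and 8 lower with the smallest p among those where all arrays of a group lay above all of the other, whether or not they passed, and for each secondary comparison the 3 higher and 3 lower chosen in the same way. Ranges cover all of these and the text gives the first ones in full. Differences between groups in the interquartile range were tested by exact permutation. Correlations of comparisons that share arrays were set beside 100 simulations without any change, with independent arrays and the same spread in each group. Simulations with the correlation within scans, and for each array left out, were added after the data were seen, as were the bins of regions by mean log2 ratio, with and without quantile normalization. R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8) and jsonlite 2.0.0 were used.

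The arrays were scanned in 6 scans, told apart by identical time stamps, on 3 days, both numbered by time. Scans 1 and 2 held DR model replicate 2 and control replicate 1 alone, scan 3 CaD replicate 3 and the other formula, scan 4 the LTF arrays, scan 5 control replicates 2 and 3 and DR model replicate 1, and scan 6 DR model replicate 3 and CaD replicates 1 and 2. Scan day 1 held scans 1, 2 and 3, day 2 held scan 4, and day 3 held scans 5 and 6. The headers used here identify slides only by position, so scan stood for slide. Scan and scan day were fitted as fixed blocks where they could be estimated, which excludes comparisons with LTF, and as random blocks for every comparison, with consensus correlations of 0.390 and 0.0968. Values within a scan or day used a mean for each group in each batch and a spread pooled over all of them, so a single array is assumed to vary like the others.

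The fit was tested on simulated data with the spreads of the 16782 regions, where known amounts were added to some regions (67 at each of the smaller sizes, 66 at the largest). For LTF against the DR model, changes of 1 on the log2 scale were recovered in 100% of cases, changes of 0.5 in 89.6% and changes of 0.25 in 7.46%, and 7 unchanged regions were called. For the diabetic groups against control the shares were 100%, 95.5% and 14.9%, with 11 unchanged regions called. The simulated arrays were independent, with the same spread in each group and no effect of scan. The data had a consensus correlation of 0.390 within scans, so these shares and false calls need not hold for them. Alternatives were quantile normalization, scaling, loess within arrays, normexp background correction with an offset of 50 (on median signals, since mean signals were not used here), the authors' table, filters on dim probes, flagged spots kept, other summaries of probes, other variance models, array weights, the replicate number and scan as blocks, and each array left out in turn. The replicates are separate rats per the labels.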

Results

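DNA methylation in the peripheral blood of male Sprague Dawley rats was profiled by methylated DNA immunoprecipitation (MeDIP) on 2-colour tiling arrays. In this assay an antibody pulls down fragments that carry methylated cytosine, and the pulled-down DNA, labelled with Cy5, is hybridised together with untreated input DNA, labelled with Cy3. A log2(MeDIP/input) ratio above 0 stands for a higher ratio of recovered to input DNA than at the median probe. The ratio also followed probe length, with a mean of 0.32 for probes of 45 nucleotides and -1.01 for those of 60. The text therefore compares groups at the same regions and does not rank regions by methylation. Outlier spots were left out array by array, 235 to 10700 of them and most in LTF. The probes averaged in a region can therefore differ between arrays. The rats were 20 weeks old and formed 5 groups of 3 biological replicates, with 1 array per rat. The groups were untreated controls, a diabetic retinopathy model (DR model) made with 45 mg/kg streptozotocin, a toxin of the insulin-producing beta cells, and 3 groups of model rats given a treatment. The first treated group received calcium dobesilate (CaD), a drug used for diabetic retinopathy, at 0.25 g/kg per day. The second received another Chinese herbal formula, whose dose the labels do not give, nor whether insulin was given with it. The last received Luo-tong formula (LTF), the herbal formula the study is named for, at 2 g/kg per day. The CaD and LTF rats also received 1.5 IU of insulin per day. The labels name distilled water and no insulin for the DR model, so an effect of the drug cannot be told apart from an effect of insulin.

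Each array measured 172669 probes. The median background-subtracted signal was between 39.0 and 75.7 intensity units for MeDIP DNA and between 45.0 and 72.9 for input DNA. MeDIP signal was well above background on 77.6% to 90.0% of the probes of an array, and input signal on 91.9% to 96.8%. The number of arrays limits the precision of the differences given here. Probes were joined into 16782 regions with a median of 10 probes and a median length of 1655 bp on the rn4 assembly. No gene is named for a region, because the files give positions without genes and the gene table at hand uses another assembly. The 16782 regions held mean log2 ratios from -2.42 to 2.24 over all arrays, and 47.0% of them lay above 0. Regions on the X chromosome, 606 in number, had a median log2 ratio of -0.18 over all arrays, and the remaining 16176 regions a median of -0.03.

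**Figure D1:**
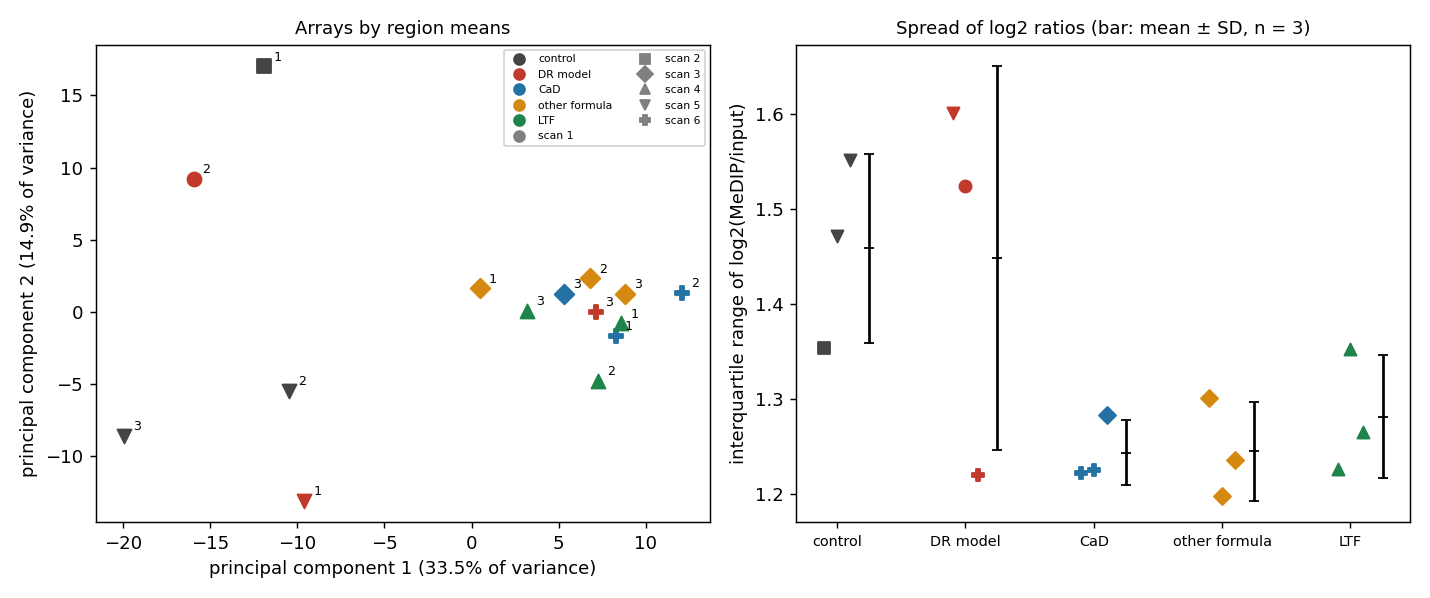
The left panel places the 15 arrays on the first principal components of the region means, with 33.5% and 14.9% of the variance, by group (colour), scan (marker) and replicate number. The right panel shows the interquartile range of the log2 ratio over the probes of each array, with the mean and SD of each group (n = 3). The controls and DR model replicates 1 and 2 lie at negative values of the first component, and DR model replicate 3 lies among the treated arrays.

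The arrays differed in the width of their log2 ratio distributions, in a way that cannot be separated from scan. The interquartile range of the log2 ratio averaged 1.46 ± 0.0995 (SD, n = 3) in controls, 1.45 ± 0.202 (SD, n = 3) in the DR model, 1.24 ± 0.0340 (SD, n = 3) with CaD, 1.25 ± 0.0521 (SD, n = 3) with the other formula and 1.28 ± 0.0644 (SD, n = 3) with LTF. The 5 groups did not differ past the threshold in an exact permutation test of the F statistic (p = 0.0715). In exact two-sided permutation tests the DR model differed from control by -0.01 (p = 0.9), CaD from the DR model by -0.20 (p = 0.4), the other formula from the DR model by -0.20 (p = 0.3) and LTF from the DR model by -0.17 (p = 0.4), where 3 arrays against 3 cannot go below p = 0.1. These tests leave out the scans: scans 1, 2 and 5, with no treated array, held arrays at 1.35 to 1.60, and within scan 6 the DR model array stood at 1.22 and the CaD arrays at 1.22 and 1.23. With normexp background correction the differences were -0.0202 for CaD and -0.00342 for the other formula, and in the authors' table -0.0336 for CaD, -0.0307 for the other formula and -0.0286 for LTF. DR model replicate 3, at 1.22, lay below the other DR model arrays, at 1.60 and 1.52, and without it the differences from the DR model were -0.32 for CaD, -0.32 for the other formula and -0.28 for LTF. Neither a wrong label nor the scan it shared with CaD replicates 1 and 2 was excluded for this array, and that doubt applies to every comparison with the DR model below. It is also the only DR model array that shared a scan with treated arrays. Without it, treatment and scan cannot be told apart, so the higher counts found without it may reflect scan.

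The comparison of the DR model with control asks which regions differ in rats with untreated diabetes. No region passed an adjusted p of 0.05 in limma, and 2134 of 16782 regions had an unadjusted p under 0.05. Without any difference and with independent arrays, a share of 0.05 of the regions is expected under that p, here and below. The regions with the smallest p among those where all arrays of the groups were separated differed by 0.34 to 0.51 on the log2 scale where the DR model was higher and by -0.52 to -0.34 where it was lower (8 regions each, adjusted p between 0.0753 and 0.111 in limma). On chromosome 13 from 88595647 to 88597261 the log2 ratio was 0.78 ± 0.03 (SD, n = 3) in controls and 0.27 ± 0.14 (SD, n = 3) in the DR model, a difference of -0.51 ± 0.08 (SE). On chromosome 6 from 46551293 to 46553048 the ratio was 0.14 ± 0.05 (SD, n = 3) in controls and -0.24 ± 0.06 (SD, n = 3) in the DR model. In the other direction, a region on chromosome 1 from 64625533 to 64627142 had -1.11 ± 0.03 (SD, n = 3) in controls and -0.72 ± 0.07 (SD, n = 3) in the DR model, and a region of the same chromosome from 163981540 to 163983288 had -1.16 ± 0.07 (SD, n = 3) and -0.71 ± 0.09 (SD, n = 3). All arrays of the groups were separated in 1933 regions, or 11.5%, where chance gives 10%. The regions were also sorted by mean log2 ratio into 5 bins of equal size. The median difference was 0.11 in the lowest bin and 0.02 in the highest.

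Control and DR model arrays shared scan 5, which held control replicates 2 and 3 and DR model replicate 1. Within that scan limma called 39 regions, and 10 with scan as a fixed block. Both counts rest on that 1 DR model array, assumed to vary like the others, and do not show that the groups differ within the scan. Within scan day 1, with 1 array of each group, 0 regions were called and 1772 had an unadjusted p under 0.05 in limma, and within scan day 3, with 2 of each, 47 regions were called. The count rose to 39 without control replicate 1, to 2 without control replicate 2, to 28 without DR model replicate 2 and to 3 without DR model replicate 3. It was 250 with loess within arrays and 98 without control replicate 1 and DR model replicate 2, each of which had a scan of its own.

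The 4 diabetic groups averaged, treated or not, differed from control in 1462 regions (adjusted p under 0.05 in limma), 1066 of them with a higher and 396 with a lower log2 ratio in diabetic rats. The called differences had a median size of 0.29 on the log2 scale and ranged from -0.65 to 0.79. The region with the smallest p lay on chromosome 8 from 17985146 to 17986876. Its log2 ratio was -1.79 ± 0.12 (SD, n = 3) in controls, -1.38 ± 0.03 (SD, n = 3) in the DR model, -1.01 ± 0.12 (SD, n = 3) with CaD, -1.10 ± 0.08 (SD, n = 3) with the other formula and -0.998 ± 0.10 (SD, n = 3) with LTF, a difference of 0.67 ± 0.06 (SE) between diabetic and control rats (adjusted p = 0.000248 in limma). The regions on chromosome 1 from 163981540 to 163983288 and on chromosome 5 from 135348474 to 135350069 were higher in diabetic rats by 0.50 ± 0.06 (SE) and 0.42 ± 0.05 (SE). These sizes depended on the processing. Over the alternatives the first region on chromosome 8 ranged from 0.17 to 0.75, and those on chromosomes 1 and 5 from 0.08 to 0.54 and from 0.16 to 0.49. The lowest values came with normexp for chromosomes 8 and 1 and in the authors' table for chromosome 5. Lower values in diabetic rats were led by a region on chromosome 8 from 126370797 to 126372423, at 1.23 ± 0.14 (SD, n = 3) in controls and between 0.66 and 0.81 in the means of the diabetic groups, followed by the regions named above on chromosomes 13 and 6, with differences of -0.43 ± 0.06 (SE) and -0.32 ± 0.05 (SE).

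Without scaling between arrays, higher calls in diabetic rats lay mostly at low and lower calls mostly at high log2 ratios. In the lowest bin of regions by mean log2 ratio, 657 were higher and 2 lower in diabetic rats, with a median difference of 0.17. In the highest bin, 9 were higher and 211 lower, with a median difference of -0.06. Over all regions the difference and the mean log2 ratio correlated at r = -0.58, a correlation across regions, which are not independent replicates. The slope of an array on the mean profile of all arrays averaged 1.12 ± 0.104 (SD, n = 3) in controls, 1.06 ± 0.135 (SD, n = 3) in the DR model, 0.918 ± 0.0414 (SD, n = 3) with CaD, 0.947 ± 0.0664 (SD, n = 3) with the other formula and 0.956 ± 0.0307 (SD, n = 3) with LTF. After quantile normalization the correlation was -0.20, the lowest bin held 144 higher and 47 lower calls, and the highest bin 23 higher and 66 lower. On the X chromosome 38 regions were higher and 7 lower, or 7.43% called, and 8.76% of the other regions were called. The group means also differed by probe length. Probes of 60 nucleotides averaged -1.11 in controls, -1.06 in the DR model, -0.95 with CaD, -1.01 with the other formula and -0.92 with LTF. Those of 45 nucleotides averaged 0.33, 0.37, 0.30, 0.29 and 0.28. The parts of probe length and of mean log2 ratio in this pattern were not separated.

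**Figure D2:**
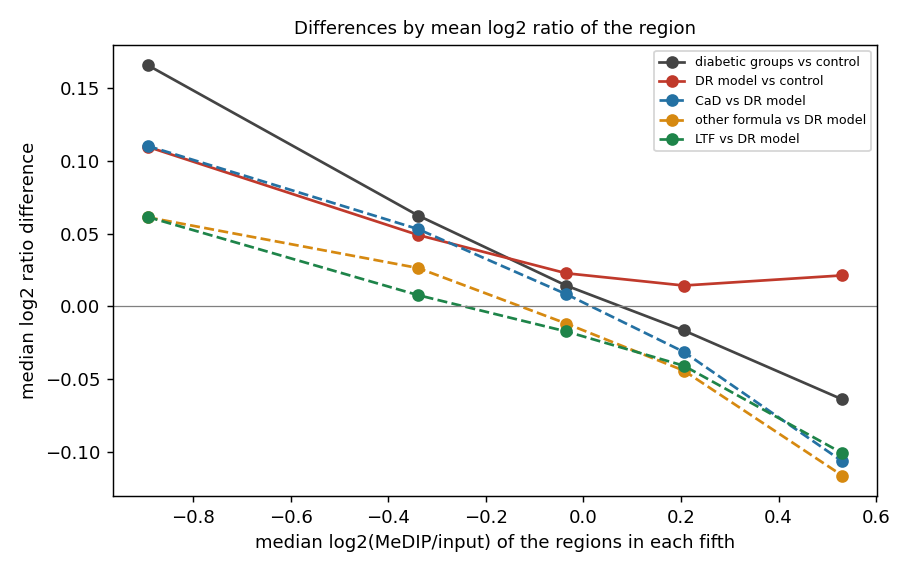
Each line joins the median log2 ratio difference of a comparison (vertical axis) in the 5 bins of the 16782 regions sorted by mean log2 ratio (horizontal axis, the median of each bin). In diabetic rats against control the median falls from 0.17 in the lowest bin to -0.06 in the highest, and for each treatment against the DR model the median in the highest bin is about -0.10 to -0.12, all without scaling between arrays.

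The count of regions that differed between diabetic and control rats was 561 after quantile normalization, 293 of them higher, and 284 with scan as a random block. Within scan day 1, with 1 control array and LTF left out, which had a day of its own, 36 regions were called, and within scan day 3 the count was 1391. On scan day 3 the control arrays were all in scan 5, as was DR model replicate 1. DR model replicate 3 and CaD replicates 1 and 2 were in scan 6. No other formula or LTF array was scanned that day. The 1391 regions therefore cover only the DR model and CaD, and diabetes and scan are not told apart in them. Leaving out control replicate 3 gave 274 regions, and leaving out CaD replicate 2 gave 908. Leaving out other formula replicate 3 gave 955, and leaving out DR model replicate 2 gave 2546. Tested singly, in comparisons added after the data were seen, CaD differed from control in 1257 regions, the other formula in 410 and LTF in 1221. With scan as a random block these counts were 1, 0 and 4, with 2690, 2010 and 2228 regions under an unadjusted p of 0.05 in limma. Over all alternatives other than single arrays left out, the counts ran from 0 to 2941, from 0 to 1758 and from 4 to 3865. Those alternatives include single probes, which are not comparable with regions. The count for CaD was 211 without control replicate 3, and 94, 1 and 702 without CaD replicates 1, 2 and 3. The count for the other formula was 774, 228 and 1 without control replicates 1, 2 and 3, and 137, 2 and 0 without its own replicates 1, 2 and 3, the last with 2449 regions under an unadjusted p of 0.05 in limma. The count for LTF was 389 without control replicate 3, and 316 and 163 without LTF replicates 1 and 2.

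The comparison of CaD with the DR model asks which regions differ in diabetic rats given this drug and insulin. No region passed an adjusted p of 0.05 in limma, and 2514 regions had an unadjusted p under 0.05. The leading separated regions differed by 0.35 to 0.66 where CaD was higher and by -0.91 to -0.32 where it was lower (8 regions each, adjusted p between 0.105 and 0.113 in limma). On chromosome 13 from 80016481 to 80017144 the log2 ratio was -0.13 ± 0.11 (SD, n = 3) in the DR model and 0.30 ± 0.08 (SD, n = 3) with CaD, and on chromosome 1 from 164180391 to 164181229 it was -1.04 ± 0.19 (SD, n = 3) and -0.38 ± 0.13 (SD, n = 3). Lower values with CaD were led by chromosome 1 from 76513343 to 76514065, at 0.29 ± 0.21 (SD, n = 3) in the DR model and -0.27 ± 0.11 (SD, n = 3) with CaD, and by chromosome 7 from 139197599 to 139198573, at 0.93 ± 0.09 (SD, n = 3) and 0.55 ± 0.04 (SD, n = 3). The median difference was 0.11 in the lowest bin of regions by mean log2 ratio and -0.11 in the highest. Scan 6 held CaD replicates 1 and 2 with DR model replicate 3, and within it 0 regions were called and 280 had an unadjusted p under 0.05 in limma. With scan as a fixed block the count was also 0, with 350 regions under an unadjusted p of 0.05 in limma. Like the 280 within scan 6, that is fewer than expected without any difference, so neither number points to a difference within scans. Within scan day 1, where 1 CaD rat stood against 1 DR model rat, the count was 33, within scan day 3 it was 0, with 1477 regions under an unadjusted p of 0.05 in limma, and without DR model replicate 3 it was 1428.

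The other formula was compared with the DR model in the same way. No region passed an adjusted p of 0.05 in limma, and 2535 regions had an unadjusted p under 0.05. The leading separated regions differed by 0.30 to 0.55 where the other formula was higher and by -0.48 to -0.36 where it was lower (8 regions each, adjusted p = 0.103 in limma for each). The region on chromosome 13 from 80016481 to 80017144 had 0.31 ± 0.08 (SD, n = 3) with the other formula, against -0.13 ± 0.11 (SD, n = 3) in the DR model. A region on chromosome 9 from 74676248 to 74677893 had -0.14 ± 0.04 (SD, n = 3) against -0.47 ± 0.05 (SD, n = 3). Lower values were led by the region on chromosome 7 from 139197599 to 139198573, at 0.53 ± 0.02 (SD, n = 3) against 0.93 ± 0.09 (SD, n = 3), and by chromosome 7 from 121620511 to 121621040, at 0.71 ± 0.05 (SD, n = 3) against 1.19 ± 0.20 (SD, n = 3). No scan held arrays of both groups. With scan as a fixed block, joined through the CaD arrays, the count was 0 and 305 regions had an unadjusted p under 0.05 in limma. That is fewer than expected without any difference. Within scan day 1, with 1 DR model array, 982 regions were called, and without DR model replicate 3 the count was 1134.

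LTF against the DR model is the comparison the study is named for. In limma 151 regions passed an adjusted p of 0.05, 40 with a higher and 111 with a lower log2 ratio under LTF. A region on chromosome 1 from 142339755 to 142341352 had -0.37 ± 0.06 (SD, n = 3) with LTF and -0.94 ± 0.08 (SD, n = 3) in the DR model, a difference of 0.58 ± 0.07 (SE, adjusted p = 0.0149 in limma). Its means in controls, CaD rats and rats on the other formula were -0.89 ± 0.11 (SD, n = 3), -0.72 ± 0.10 (SD, n = 3) and -0.81 ± 0.07 (SD, n = 3). A region on chromosome 4 from 152878080 to 152878642 was higher under LTF by 0.52 ± 0.08 (SE). The lowest p among lower regions belonged to chromosome 1 from 82039053 to 82039420, a region of 3 probes, at -0.38 ± 0.06 (SD, n = 3) with LTF and 0.12 ± 0.11 (SD, n = 3) in the DR model. That difference was -0.50 ± 0.07 (SE, adjusted p = 0.0152 in limma) and -0.02 in the authors' own table. A region on chromosome 20 from 4040890 to 4041642 was lower under LTF by -0.53 ± 0.08 (SE). The 16 leading separated regions all passed the threshold, with differences of 0.43 to 0.74 where LTF was higher and of -0.62 to -0.38 where it was lower.

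Among the bins of regions by mean log2 ratio, the lowest held 20 regions that were higher and 3 that were lower under LTF, and the highest held 0 that were higher and 44 that were lower. After quantile normalization these were 25 and 21 in the lowest bin and 4 and 19 in the highest. The LTF arrays had a scan and a scan day of their own, so scan and treatment cannot be told apart in this comparison, and with scan as a random block 0 regions passed and 1470 had an unadjusted p under 0.05 in limma. The count was also 0 when only the arrays of these groups were fitted, with 2330 regions under an unadjusted p of 0.05 in limma. In limma it was 0 without LTF replicate 1 (2416 regions under an unadjusted p of 0.05), 5 without LTF replicate 2, 5 without LTF replicate 3, 0 without DR model replicate 1 (2601 regions under an unadjusted p of 0.05), 5 without DR model replicate 2 and 1307 without DR model replicate 3.

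**Figure D3:**
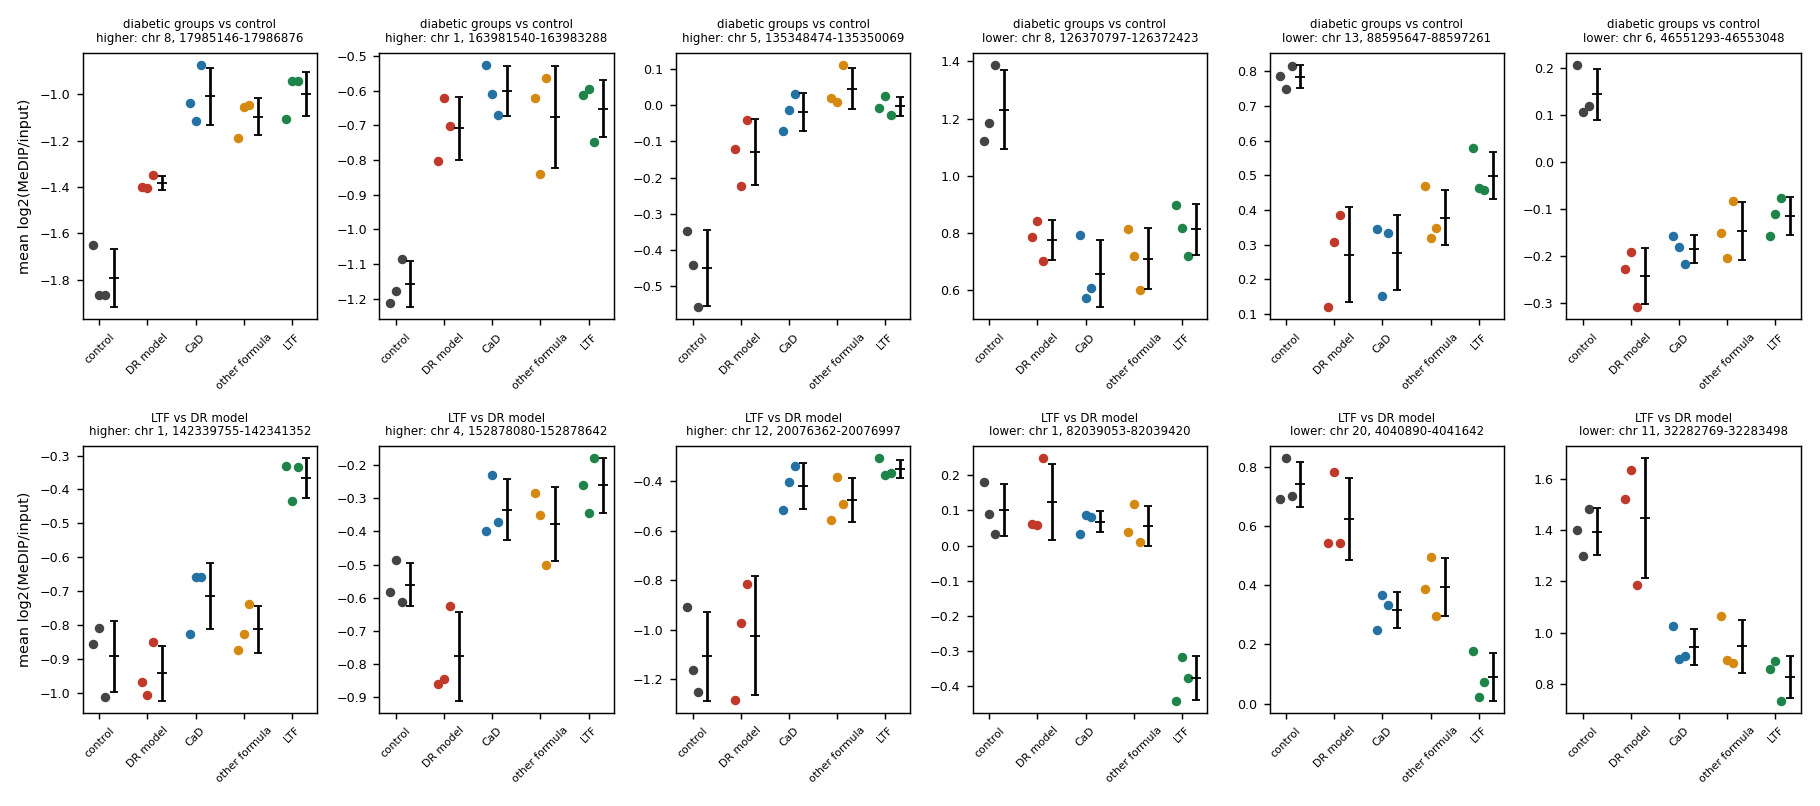
Points show the mean log2(MeDIP/input) of each array over the probes of a region (vertical axis), by group, and bars the mean and SD of each group (n = 3). The upper row holds the 3 higher and 3 lower regions of diabetic rats against control, and the lower row the first 3 of each direction for LTF against the DR model. In the first upper panel the controls average -1.79 and the DR model -1.38, and in the first lower panel LTF averages -0.37 and the DR model -0.94.

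The 3 treated groups averaged differed from the DR model in 336 regions (adjusted p under 0.05 in limma), 72 with a higher and 264 with a lower log2 ratio. The regions on chromosome 13 from 80016481 to 80017144, chromosome 12 from 20076362 to 20076997 and chromosome 4 from 152878080 to 152878642 were higher by 0.42 ± 0.06 (SE), 0.61 ± 0.09 (SE) and 0.45 ± 0.07 (SE). The regions on chromosome 7 from 139197599 to 139198573 and on chromosome 1 from 76513343 to 76514065 were lower by -0.39 ± 0.05 (SE) and -0.51 ± 0.07 (SE), as was a region of unplaced sequence from 25164053 to 25165834, by -0.36 ± 0.05 (SE). Over the alternatives the chromosome 1 region ranged from -0.90 with the median over probes to -0.08 with normexp. The chromosome 7 region ranged from -0.44 to -0.18, and the unplaced region from -0.39 to -0.16. Of the 336 regions, 184 that were lower and 1 that was higher lay in the highest bin by mean log2 ratio, and 0 that were lower and 28 that were higher in the lowest bin. After quantile normalization the highest bin held 9 lower and 0 higher calls in limma and the lowest bin 2 of each. The count was 33 after quantile normalization and 0 with scan as a random block, with 2413 regions under an unadjusted p of 0.05 in limma. It was 2335 without DR model replicate 3, 0 without DR model replicate 1 or 2, with 2428 and 2318 regions under an unadjusted p of 0.05 in limma, and between 15 and 199 without any single treated array, with 15 for other formula replicate 3 and 199 for LTF replicate 2.

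LTF was also set against the other treatments. LTF and CaD differed in 3 regions, all lower under LTF (adjusted p = 0.0472 in limma for each). The region on chromosome 1 from 82039053 to 82039420 differed by -0.45 ± 0.07 (SE), with 0.07 ± 0.03 (SD, n = 3) under CaD. A region on chromosome 8 from 114794468 to 114796002 had -0.74 ± 0.06 (SD, n = 3) with LTF and -0.21 ± 0.05 (SD, n = 3) with CaD, and a region on chromosome 13 from 87111682 to 87113374 had -1.03 ± 0.12 (SD, n = 3) and -0.49 ± 0.04 (SD, n = 3). The count was 0 without any 1 of the 6 arrays compared, with 846 to 1257 regions under an unadjusted p of 0.05 in limma. It was also 0 with scan as a random block, the LTF arrays having a scan of their own. There 380 regions had an unadjusted p under 0.05 in limma, fewer than expected without any difference. In the authors' table the count was 0 as well (1247 regions under an unadjusted p of 0.05 in limma). The differences there were 0.00726, -0.0544 and -0.0879 in the regions on chromosomes 1, 8 and 13. LTF and the other formula differed in 0 regions in limma, with 1202 under an unadjusted p of 0.05. Over the alternatives other than single arrays left out, that count ran from 0 to 278, and the count for LTF against CaD from 0 to 220. Array weights gave the highest count in both. The region nearest to the threshold on the higher side, on chromosome 3 from 68657859 to 68659655, had -0.26 ± 0.08 (SD, n = 3) with LTF and -0.76 ± 0.12 (SD, n = 3) with the other formula (adjusted p = 0.0794 in limma), a difference that was -0.02 when only probes with both channels well above background were kept.

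The last question was whether treatment moved regions back from the diabetic change. Across the 16782 regions the difference between the DR model and control correlated with the difference between treatment and the DR model at r = -0.06 for CaD, -0.18 for the other formula and -0.13 for LTF. The DR model arrays enter both differences with opposite sign, and with no change at all simulated regions gave r = -0.50 in each case. That simulation treats the arrays as independent and every group as equally variable. With a correlation of 0.390 within scans it gave -0.28 for CaD, -0.34 for the other formula and -0.34 for LTF. The covariances were -0.00105 for CaD, -0.00301 for the other formula and -0.00239 for LTF, each above its simulated value of -0.00449, by 0.00344, 0.00149 and 0.00211. The 3 treatment differences correlated with each other. CaD and the other formula gave r = 0.86, CaD and LTF 0.72, and the other formula and LTF 0.71. The shared DR model arrays alone gave 0.50 in simulation, a value that follows from giving every group the same spread. The covariances of the treatment differences were 0.0161, 0.0150 and 0.0141, against 0.00448, 0.00449 and 0.00449 simulated. The 3 DR model arrays cannot be split into parts of at least 2, so part of these values may come from the shared arrays. The simulated values again leave out the scans and any difference in spread between groups. Fitted array weights, lower for noisier arrays, were 0.41 to 0.69 for the DR model and 0.89 to 3.61 for treated arrays. Noisier DR model arrays alone would raise these correlations above 0.50, by an amount not simulated. Values above 0.50 therefore do not show that the treatments act alike. Without DR model replicate 3 the correlations of the treatment differences with the DR model difference were -0.42, -0.48 and -0.41 for CaD, the other formula and LTF, where simulation without any change gave -0.60 for each. The covariances then lay below their simulated values, by -0.00385, -0.00472 and -0.00355, so the side on which they fell depended on this array. The correlation for CaD was 0.105 with loess within arrays, -0.18 with quantile normalization and -0.20 with scaling to the same median absolute deviation or with normexp. For the other formula these were -0.0531, -0.31, -0.36 and -0.32, and for LTF -0.0385 with loess and -0.25 with that scaling. Whether treatment moved regions back was therefore left open.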

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

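Among the tests in this part, those of scale, of scan day and of the scan of the LTF arrays were chosen after the results were seen, and the others before the data were examined. A difference between groups flagged 4 results, all from the direct comparison of the LTF and CaD effects: the count of 3 regions past an adjusted p of 0.05 in limma, and the differences of -0.45 on chromosome 1 from 82039053 to 82039420, of -0.53 on chromosome 8 from 114794468 to 114796002 and of -0.53 on chromosome 13 from 87111682 to 87113374. Of the 10 splits of these 6 arrays, only the real one, 1 of 10, had as many as 3 regions, which is the smallest share that 3 arrays against 3 can reach and leaves chance open.

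For the 1462 regions that differed between diabetic and control rats, only the real labeling, 1 of 100 drawn, had as many regions, and the highest other had 119. The labelings were drawn without regard to scan, though arrays of the same scan were correlated (consensus 0.390). This share therefore does not measure chance for these arrays. A difference between arrays in the overall distribution of log2 ratios does not account for 478 of them. These were also among the 561 regions called after quantile normalization (293 higher), in the same direction. The highest other labeling then had 4 regions, but it too was drawn without regard to scan and does not measure chance. The other 984 stay open. Quantile normalization does not equalise the slope of an array on the mean profile. The correlation of difference and mean log2 ratio was still -0.20 after it. Regions were still called when each array was scaled by its slope, with the count given further below. Which of these regions were among them was not examined, so a difference in slope is not excluded for any single one. With scan day as a term and LTF left out, 1728 regions differed, and 682 without the term. For scan, the 1462 regions with the smallest p on the arrays outside scan 5 were chosen, whether or not they passed. Control replicate 1 was the only control there, and these are not the 1462 called regions. Of the chosen ones, 71.5% had the same direction in the DR model array of scan 5 against the controls of that scan. The other ways of splitting the arrays of scan 5 gave at most 41.9%. All these shares come from the same arrays, so a high share for the DR model array pushes the others down. The others are therefore no separate yardstick. By the rule set beforehand a share above 60% was to exclude the scan. This reading was changed after the value was seen, because 1 DR model array excludes nothing. The DR model alone differed from control in 0 regions, and CaD, the other formula and LTF in 1257, 410 and 1221. Diabetes, scan, the treatments and the insulin given with CaD and LTF may therefore all contribute, and they cannot be told apart here.

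For the 151 regions that differed between LTF and the DR model, 1 of 10 splits had as many, the real one, and the highest other had 0. The overall distribution of log2 ratios of the arrays does not account for 106 of them, which were among the 175 regions called after quantile normalization. The other 45 stay open. A difference in the slope of arrays on the mean profile is not excluded by that step, after which difference and mean log2 ratio correlated at -0.06. With scan as a random block 0 regions passed in limma and 1470 had an unadjusted p under 0.05. All LTF arrays and no others were in scan 4, so treatment, insulin and scan cannot be told apart, and each could give such regions.

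Some arrays of different groups that shared a scan deviated together from their group means. The mean correlation of these deviations was 0.111 over 7 pairs in the same scan and -0.00896 over 83 pairs in different scans (exact permutation p of the difference = 0.0185, one-sided, the smallest that the 54 distinct values allow). This came from 3 pairs in scans 5 and 6, at 0.178, 0.328 and 0.322, while the other 4 pairs, among them all 3 of scan 3, lay between -0.0894 and 0.0825. An effect of some scans fits the mean, but not every pair shows it. No biological explanation was tested.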

How the results depend on the processing

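The alternatives of scaling by slope, gaps up to 1000 bp, regions missing on an array kept, values within a scan day, and leaving out the arrays with a scan of their own were chosen after seeing the data. All others were set before, those by slide with scan standing for slide, a substitute chosen after seeing the data. The values of named regions kept their direction and side of the threshold in 1968 cases and reversed in 4. They passed it only under the alternative in 187 and fell short only under the alternative in 289. These totals pool comparisons, and where no named region passed, a kept value is one that still fell short. For LTF against the DR model, 216 of 409 values were kept and 193 fell short. For LTF against CaD 52 of 155 fell short. For treated rats 41 of 189 fell short, and for diabetic rats 3 of 209. The reversed ones were chromosome 1 from 82039053 to 82039420 for LTF against CaD (0.00726 in the authors' table), chromosome 14 from 107210732 to 107211936 for the DR model against control (-0.0510 with both channels well above background), and chromosome 3 from 68657859 to 68659655 for LTF against CaD (-0.0395) and the other formula (-0.0171), both with that filter. The cause was not tested for these or the changes below, except that fewer arrays or regions entered where some were left out. Median signals over background were 39.0 to 75.7 for MeDIP DNA, and whether they limit the precision of dim probes was not tested. Gene list tests, with an estimated correlation or fry as alternatives, and the germline and housekeeping check were not run, for lack of gene names.

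Counts of regions are in limma and stand beside main counts of 0 for the DR model against control, CaD and the other formula against the DR model, 151 for LTF against the DR model (40 higher), 3 and 0 for LTF against CaD and the other formula, 1462 for diabetic rats against control (1066 higher) and 336 for treated rats against the DR model (72 higher). Main counts of 0 had 2134, 2514, 2535 and 1202 regions under an unadjusted p of 0.05. Quantile normalization gave 3 for CaD and 1 for the other formula against the DR model, 22 for LTF against the other formula, 561 for diabetic rats (293 higher), 33 for treated rats, and 175 for LTF against the DR model (64 higher). Scaling to the same median absolute deviation gave 3 for CaD, 295 for LTF, 8 and 11 for LTF against CaD and the other formula, 573 for diabetic and 50 for treated rats. Scaling by slope gave 4, 3, 5, 729 and 55 for CaD, the other formula, LTF against the other formula, diabetic and treated rats. Loess gave 250 for the DR model, 0 for LTF against CaD (1384 under an unadjusted p of 0.05 in limma) and 3368 for diabetic rats (1907 higher). Normexp gave 5, 14 and 344 (138 higher) for CaD, the other formula and LTF, 16 and 7 for LTF against CaD and the other formula, 2028 for diabetic rats (1895 higher) and 478 for treated rats (261 higher). The authors' table gave 1, 14 and 105 for the DR model, CaD and the other formula, 155 for LTF (69 higher), 0 for LTF against CaD (1247 under an unadjusted p of 0.05 in limma), 1666 for diabetic rats (964 higher) and 576 for treated rats (264 higher).

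Keeping flagged spots gave 325 for LTF, 0 for LTF against CaD (1139 under an unadjusted p of 0.05 in limma) and 743 for treated rats. Input well above background gave 264, 0 (1308 under an unadjusted p of 0.05 in limma) and 731 for the same comparisons. Both channels well above background gave 13, 196 and 634 for CaD, the other formula and LTF, 5 and 3 for LTF against CaD and the other formula, and 1303 for treated rats. The median over probes gave 2 for the other formula, 7 for LTF against the other formula, 588 for diabetic and 196 for treated rats. Regions of at least 5 probes, and gaps up to 1000 bp, gave 0 for LTF against CaD (1220 and 1248 under an unadjusted p of 0.05 in limma). Single probes, tested as 149550 probes and so not comparable with counts of regions, gave 2, 10, 42 and 2668 for the DR model, CaD, the other formula and LTF, 0 (10328 under an unadjusted p of 0.05 in limma) and 1 for LTF against CaD and the other formula, 3846 for diabetic and 6095 for treated rats. Fitting only the groups compared gave 0 for LTF (2330 under an unadjusted p of 0.05 in limma) and 3 for LTF against the other formula. Trend and robust variances gave 7, 11, 1 and 348 for the DR model, CaD, the other formula and LTF, 1 for LTF against the other formula and 676 for treated rats. Array weights gave 5 for LTF, 220 and 278 for LTF against CaD and the other formula, and 1 for treated rats.

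Scan as a fixed block gave 10 for the DR model. Scan as a random block gave 0 for LTF, for LTF against CaD and for treated rats (1470, 380 and 2413 under an unadjusted p of 0.05 in limma) and 284 for diabetic rats. Scan day as a random block gave 2 for LTF and 0 for LTF against CaD (969 under an unadjusted p of 0.05 in limma). Within scan 5 the DR model had 39, within scan day 3 it had 47, and within scan day 1 CaD had 33, the other formula 982, diabetic rats 36 and treated rats 1083, where scan 5 and scan day 1 held 1 DR model array and scan day 1 held 1 control array and 1 CaD array. Without the arrays with a scan of their own, the DR model had 98, CaD 1, LTF 16, LTF against the other formula 3, diabetic rats 2281 and treated rats 1.

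With the replicate number as a block, LTF had 27, LTF against CaD 0 (1172 under an unadjusted p of 0.05 in limma), treated rats 127 and diabetic rats 997. With this block and loess, the DR model had 147, LTF 35, LTF against CaD 0 (1262 under an unadjusted p of 0.05 in limma), diabetic rats 2857 and treated rats 100. Same-numbered arrays of different groups correlated at -0.424 to 0.331 in their deviations, 5 of 30 pairs over 0.1, and 1 of 15 arrays correlated best with its own number, so the arrays share only a number.

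With single arrays left out, a lone group being assumed to vary like the others, counts ranged from 0 to 39 for the DR model, 0 to 1428 for CaD, 0 to 1134 for the other formula, 0 to 1307 for LTF, 274 to 2546 for diabetic and 0 to 2335 for treated rats, and were 0 for LTF against CaD and the other formula (846 to 1257 and 844 to 1217 under an unadjusted p of 0.05 in limma). The correlations of treatment and DR model differences ranged from -0.421 to 0.00149 for CaD, -0.478 to -0.0911 for the other formula and -0.410 to -0.0518 for LTF. Without any change, simulation gave -0.601 to -0.446, -0.598 to -0.444 and -0.600 to -0.445, depending on the array left out, so these values are not on the same footing. The interquartile range differed by -0.0868 to 0.104 for the DR model, -0.319 to -0.128 for CaD, -0.317 to -0.127 for the other formula and -0.281 to -0.0906 for LTF. These correlations were -0.18 and -0.31 for CaD and the other formula with quantile normalization, -0.20, -0.36 and -0.25 for CaD, the other formula and LTF with scaling to the same median absolute deviation, 0.105, -0.0531 and -0.0385 with loess, -0.20 and -0.32 for CaD and the other formula with normexp, -0.16 and -0.31 with scaling by slope, and -0.18 for CaD with the median over probes. The interquartile range differed by -0.0202 for CaD and -0.00342 for the other formula with normexp, and by -0.0336, -0.0307 and -0.0286 for CaD, the other formula and LTF in the authors' table.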

Other observations

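The test of the X chromosome in this part was chosen after the results were seen, and the others before the data were examined. Probes of 45 nucleotides averaged a log2 ratio of 0.32 over the arrays and probes of 60 nucleotides -1.01, and over regions the mean probe length and the mean log2 ratio correlated at r = -0.68. Chromosomes 3, 1 and 8 had the highest shares of regions that differed between diabetic and control rats, 11.9%, 11.7% and 11.1%. Over all regions the share was 8.71%. The shares by chromosome were neither tested nor matched for mean log2 ratio. Regions called in the same direction lay beside each other in 187 pairs, 176 higher and 11 lower, where 1000 shuffles of the calls gave at most 154. Such neighbours were a median of 35413 bp apart, and all neighbours 48330 bp. X chromosome regions, set against autosomal regions of the same mean log2 ratio, differed between diabetic and control rats by 0.00908 (exact permutation p = 0.609). The rule first written for this test was to read such a p as no difference, and it was changed after the value was seen, because 3 control arrays leave it undecided.

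The number of regions past an adjusted p of 0.05 in limma was also counted for every split of the 6 arrays of a comparison. For the DR model against control all 10 of 10 splits had at least the real count of 0, beside 2134 regions under an unadjusted p of 0.05, and the highest, 509, came from control replicate 1 with DR model replicates 2 and 3 against the rest, which follows scan 5. For CaD, for the other formula and for LTF against the other formula, 10 of 10 splits had as many as the real count of 0 in limma, beside 2514, 2535 and 1202 regions under an unadjusted p of 0.05. For the treated groups against the DR model, 2 of 100 labelings had at least the real 336 regions, and the other, with 425, took DR model replicates 1 and 2 with other formula replicate 1 as the model. These labelings too were drawn without regard to scan. With the mean of all arrays taken off each region, DR model replicate 3 correlated at 0.272 with the treated mean and at -0.445 with the control mean. DR model replicates 1 and 2 correlated at -0.527 and -0.686 with the treated mean, and at 0.207 and 0.456 with the control mean. Taking off that mean pushes control and treated values toward opposite signs, so the values are not separate evidence. They are not correlations of the log2 ratios themselves. DR model replicate 3 may be mislabelled or may carry an effect of scan 6, which it shared with CaD replicates 1 and 2, and neither was excluded. Without it the counts of 0, 0, 151 and 336 for CaD, the other formula, LTF and treated rats against the DR model were 1428, 1134, 1307 and 2335 in limma. No other DR model array shared a scan with treated arrays, so these higher counts cannot be told apart from an effect of scan.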
